A study of Homo sapiens with 4 samples.

How the data were processed

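Gene expression was measured in MCF-7 cells, an established oestrogen receptor positive human breast cancer line, on Affymetrix Human Gene 1.0 ST arrays. These arrays carry short probes along the whole length of each transcript, and a probe set summarises the probes of one transcript cluster. Per the labels, cells were exposed for 48 h to 10 µM 6-shogaol or to vehicle (0.1% DMSO), and total RNA was converted to biotin-labelled single-stranded DNA before hybridisation. Each group had 2 arrays. The labels do not say whether these came from separate cultures, so the spread between arrays may be technical. No p-value here can be taken to measure variation between cultures. Gene p-values of the main fit rest on the spread between these arrays, pooled over genes. List p-values from camera, described below, compare the genes of a list with all other genes under a preset or estimated correlation.

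The deposited values are log2 expression values, 1 per probe set and array, for 33297 probe sets. Per the submitters' processing notes, GCOS, Affymetrix Expression Console and RMA were used; no versions are given there. RMA corrects the background, normalises the arrays against each other and summarises each probe set on the log2 scale. The authors' annotation release and genome build are not given in the sources used here, so no coordinates are printed. The table gives no detection calls and no raw probe signals, so no probe set was called absent, and the number of arrays limits the precision. Slides and scan dates are not given in the sources used here, and no batch was tested.

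Probe sets were named from GEO's platform annotation. Of the 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none there. Symbols were checked through their gene identifiers against the RefSeq annotation of GRCh38.p14, used for names only: 0 symbols needed an update and 31 probe sets had an identifier that the table does not hold. Only probe sets with 1 symbol entered the gene table. For the 769 genes with several probe sets, the one with the highest mean over all 4 arrays was used, which left 18417 genes.

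The comparison of 6-shogaol with vehicle was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, all 4 arrays, no covariates). Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 18417 genes. Standard errors (SE) of log2 fold changes are limma's moderated ones. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 27 lists, and again with the correlation estimated from the residuals and with fry, whose directional test asks whether a list moves on balance one way and whose mixed test asks whether its genes change in either direction. The 27 lists, all with at least 5 measured members, were written from textbook knowledge before the data were examined, as were the tests, the other settings to be tried and the rule for named genes. Of 671 listed genes 607 were measured; the others had no probe set with a single symbol. Several lists share members, and 30 of the changed genes were in at least 1 list. A list cannot be read as proof of the pathway in its name.

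The named genes are the 12 with the largest rise and the 12 with the largest fall among changed genes whose 6-shogaol arrays both lay beyond both vehicle arrays. To these were added up to 4 members with the smallest p of each list that passed its test or held a changed gene, up to 2 of every other list, and PPARG, ESR1, NFE2L2 and ATF4 whatever their values; TP53, also meant to be named, had no probe set with it as the only symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

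The other settings were the replicate number as a block, leaving out each array in turn, quantile normalisation of the deposited values, centring of each array on its median, a trended and robust prior, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, all probe sets in place of genes, a minimum change of 2-fold, and an unmoderated fit. A robust prior, alone and together with 2 of these, was added after seeing the data. The fit was tested on simulated data with the real gene means and with gene variances drawn from limma's fitted prior, equal in both groups. Over 10 draws of 18417 genes with 200 changed, 29.0% of 1.5-fold, 96.4% of 2-fold and 100% of 4-fold changes were recovered. The mean number of false calls was 7.3. The draws take that prior for granted. They leave out the wider spread between the 6-shogaol arrays (median SD 0.13, against 0.078 for vehicle) and the trend of their difference on intensity. In the same draws a list of 30 genes shifted by 0.3 on the log2 scale was found in 10 of 10 draws at the preset correlation and in 0 of 10 with the estimated one, and 0 of 200 unshifted lists were called at the preset correlation. The simulated genes varied independently, so this does not test the preset correlation on correlated genes.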

Results

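MCF-7 breast cancer cells were exposed for 48 h to 10 µM 6-shogaol, a pungent phenol of dried ginger that carries an α,β-unsaturated ketone, or to the DMSO vehicle, and their transcripts were profiled on whole-transcript arrays. The comparison asks which transcripts differ between treated and vehicle cells. There were 2 vehicle and 2 6-shogaol arrays, with 18417 genes tested. The arrays were close to each other over all probe sets. Pearson's r across probe sets, which are not independent replicates, was 0.993 between the vehicle arrays, 0.989 between the 6-shogaol arrays, and 0.989 to 0.991 between groups. The spread of gene values was narrower on 6-shogaol replicate 2, with an interquartile range of 2.68 on the log2 scale against 2.95 on 6-shogaol replicate 1, 2.95 on vehicle replicate 1 and 2.88 on vehicle replicate 2.

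After 6-shogaol, 72 genes rose and 100 fell. The largest rise was that of CYP1A1, a cytochrome P450 of xenobiotic metabolism and a classical target of the aryl hydrocarbon receptor (AHR), from 5.31 ± 0.21 to 8.38 ± 0.66 log2 units (SD, n = 2 each), or 8.41-fold. GDF15, a stress-induced cytokine, followed at 4.75-fold (from 8.06 ± 0.13 to 10.30 ± 0.32, SD, n = 2 each). The largest falls were those of the long non-coding RNA LINC00052, 3.28-fold lower, and of KLHL4, 2.97-fold lower. By limma with Benjamini-Hochberg adjustment, the adjusted p was 2.42e-06 for CYP1A1 and GDF15 and 0.000129 for LINC00052 and KLHL4. Most changes were small. Of the called genes, 16 rose and 9 fell by at least 2-fold, and the smallest called change was 1.54-fold. At an unadjusted p under 0.05 there were 1975 genes, of which 791 were higher and 1184 lower, where chance alone would give about 921.

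The number of called genes depended on limma's pooling of the spread across genes and on other settings. An unmoderated fit, which differs only in that pooling, called 0 genes (1275 at an unadjusted p under 0.05). A fit over all probe sets called 0 (2487 probe sets at an unadjusted p under 0.05), and a fit after renewed quantile normalisation called 1 gene, GDF15. These 2 fits also change the tests or the values, so they do not isolate the pooling. Leaving out any 1 array also lowered the number of calls, but the counts of these fits cannot be compared with each other. The spread then came from the group that kept both arrays. Without a vehicle array the pooling gave every gene the same variance, and without a 6-shogaol array it did not. All 172 genes kept their direction in each of the gene-level fits above. Except after renewed quantile normalisation, that kept direction was fixed in advance. In that fit a reversal was unlikely too, since every called change was at least 0.62 on the log2 scale. The unmoderated fit shares the fold changes of the main fit. For every called gene both 6-shogaol arrays lay beyond both vehicle arrays, so leaving out 1 array could not reverse it. Such separation held for 40.4% of all genes, against 33.3% by chance. These limits hold for every gene call below.

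HSPB8, a small heat shock protein, rose by 1.54 on the log2 scale (SE 0.22, adjusted p = 0.00283 by limma). SLC7A11, the cystine transporter that feeds glutathione synthesis, rose by 1.33 (SE 0.17, adjusted p = 0.00112 by limma). DDIT3, which encodes the transcription factor CHOP, rose by 1.31 (SE 0.18), CDKN1A, the cyclin-dependent kinase inhibitor p21, by 1.26 (SE 0.16), and GADD45A, a DNA damage and growth arrest gene, by 1.16 (SE 0.18). MIR21, APOBEC3H, TSPAN1, CEACAM5 and SNORD116-6 rose between 2.04-fold and 2.36-fold. The MIR21 probe set does not tell the mature microRNA from its precursor or host transcript, and SNORD116-6 belongs to a family of near-identical copies and was among the dimmest genes (3.92 ± 0.65 log2 units after 6-shogaol, SD, n = 2), so both are uncertain as gene-level values.

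NPY1R, the neuropeptide Y receptor, fell by 1.29 on the log2 scale (SE 0.15, adjusted p = 0.000792 by limma). DKK1, a secreted Wnt antagonist, fell by 1.22 (SE 0.15), CAV1, the caveolar coat protein caveolin-1, by 1.19 (SE 0.16), and COL12A1, a fibril-associated collagen, by 1.15 (SE 0.15). MME, a membrane metallopeptidase, the chemokine CXCL12, the sulphate transporter SLC26A2, the matrix protein MGP, the semaphorin SEMA3A and the amino acid transporter SLC6A14 were between 1.90-fold and 2.16-fold lower.

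**Figure D1:**
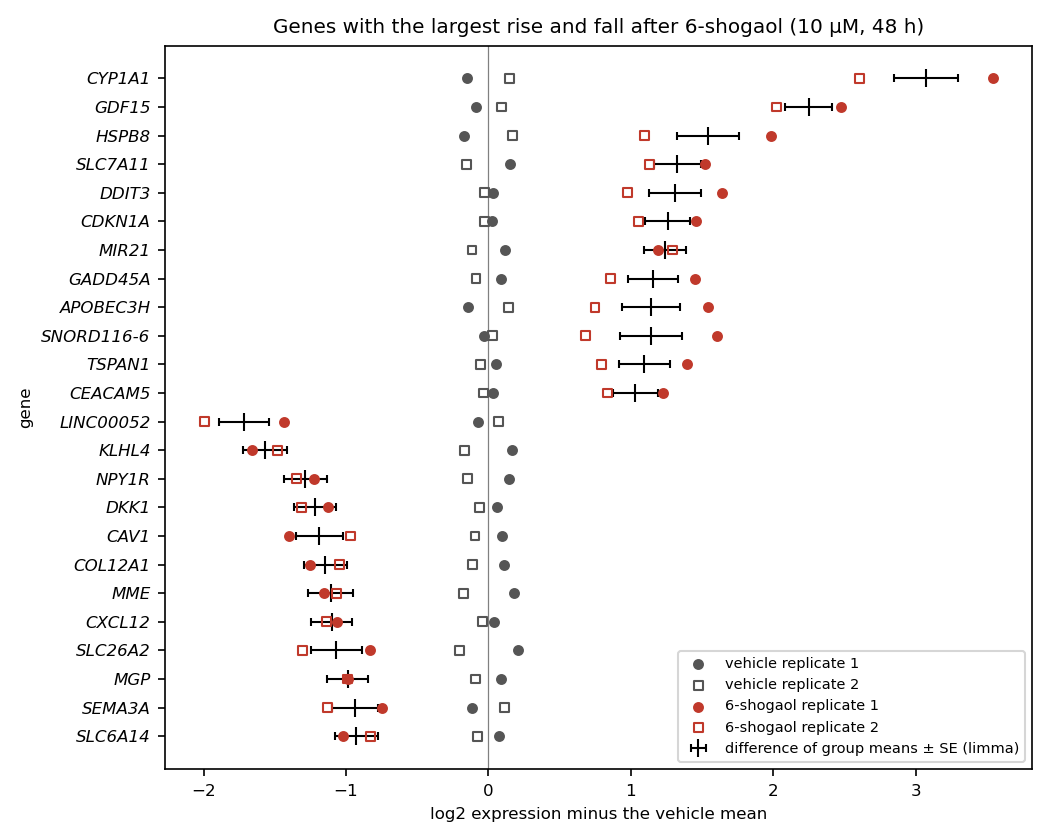
Log2 expression of the 12 genes with the largest rise and the 12 with the largest fall on each array, relative to the vehicle mean of that gene (x axis, log2 units; y axis, genes). Circles are replicate 1 and squares replicate 2, in grey for vehicle and red for 6-shogaol; the black mark is the difference of group means with its limma SE, from 3.07 for CYP1A1 to -1.72 for LINC00052, and both 6-shogaol arrays lie beyond both vehicle arrays for each gene.

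Of the 27 gene lists fixed before the data were examined, 9 shifted up and 5 shifted down by camera at the preset correlation. None of the 27 passed with a correlation estimated from these 4 arrays (the smallest unadjusted p was 0.0584, for AHR targets) or with fry's directional test (smallest unadjusted p 0.00502, for the interferon response), whereas 13 passed fry's mixed test, which takes changes in either direction. Those 13 do not back the camera calls as a group, since the p53, mitosis, replication, ER chaperone, hypoxia, autophagy and cholesterol lists missed the mixed threshold (adjusted p from 0.0520 to 0.0785), while the heat shock, fatty acid, tubulin, luminal, stem cell, and fibroblast and leukocyte lists passed it (adjusted p from 0.00171 to 0.0476) without passing camera. The metallothionein, PPAR, oestrogen receptor, mesenchymal, NRF2, ATF4 and AHR lists passed both camera at the preset correlation and fry's mixed test (adjusted p of the latter from 0.00400 to 0.0476). The mixed test says nothing about their direction. The adjusted p with an estimated correlation is given below beside each of the 14 lists that passed at the preset correlation, and was 0.578 or more for each of the other 13. All other camera values below are at the preset correlation. With an estimated correlation, the simulated list shift of 0.3 was found in 0 of 10 draws. Missing that threshold therefore cannot show that a list was unshifted. For the 14 lists the estimates, which rest on 4 arrays, ran from 0.051 (PPAR targets) to 0.60 (p53 targets), all above the preset 0.01. The p-values at the preset correlation may therefore be far too small.

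Targets of p53 had the highest median of the 27 lists, 0.50 on the log2 scale. Of 27 measured members 7 rose, 0 fell and 20 did not pass, and 18 rose when adjusted over the list alone. Besides GDF15, CDKN1A and GADD45A, TP53INP1, a p53-induced stress gene, rose by 0.86 (SE 0.15, adjusted p = 0.0154 by limma), and 24 of the 27 members had a higher mean after treatment. The list passed camera (adjusted p = 1.57e-19 at the preset correlation, adjusted p = 0.578 with an estimated correlation).

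Targets of AHR had a median of 0.38, and 3 of 10 measured members rose, 0 fell and 7 did not pass (6 rose when adjusted over the list alone). CYP1B1, a second cytochrome P450 under AHR control, rose 1.93-fold from an already high level of 10.76 ± 0.07 to 11.71 ± 0.11 log2 units (SD, n = 2 each), and SLC7A5, a large neutral amino acid transporter, rose 1.96-fold. NEDD9 was 1.49-fold higher (adjusted p = 0.0768 by limma, not past the threshold). The camera adjusted p was 4.09e-09 at the preset correlation, and adjusted p = 0.578 with an estimated correlation.

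Targets of NRF2, the transcription factor of the antioxidant response, had a median of 0.24. Of 34 measured members 4 rose, 0 fell and 30 did not pass (7 rose when adjusted over the list alone). By mean, 27 were higher and 7 lower, among the latter GCLC (-0.07) and GCLM (-0.06), neither past the threshold. Those that rose were SLC7A11, ABCC3, an organic anion exporter, at 1.95-fold, TXNRD1, thioredoxin reductase, at 1.73-fold, and HMOX1, haem oxygenase 1, at 1.68-fold (adjusted p = 0.0464 by limma, the weakest of them). The transcript of NRF2 itself, NFE2L2, differed by 0.09 (SE 0.15, not past the threshold). The list's camera adjusted p was 4.09e-09 at the preset correlation, and adjusted p = 0.578 with an estimated correlation.

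Among genes of the ATF4 and amino acid response, 5 of 35 measured members rose, 0 fell and 30 did not pass. Adjusted over the list alone, 9 rose and 1 fell, namely PSAT1 (-0.51 on the log2 scale). The 5 that rose over all genes were SLC7A11, DDIT3, SLC7A5, the mTOR inhibitor DDIT4 at 1.58-fold and the secreted glycoprotein STC2 at 1.60-fold. The ATF4 transcript differed by 0.08 (SE 0.14, not past the threshold). The list median was 0.10 with a camera adjusted p of 3.12e-05 at the preset correlation, and adjusted p = 0.615 with an estimated correlation. Endoplasmic reticulum chaperone and folding genes had a median of 0.23, with 1 of 21 members risen, 0 fallen and 20 not past the threshold (5 rose when adjusted over the list alone). HERPUD1, an ER-associated degradation factor, rose 1.66-fold, and HSPA5, the chaperone BiP, was 1.42-fold higher without passing, as were ERO1B at 1.48-fold and SEC24D at 1.40-fold. The camera adjusted p was 2.10e-06 at the preset correlation, and adjusted p = 0.578 with an estimated correlation. Without 6-shogaol replicate 1 the ATF4 list no longer passed (adjusted p = 0.159 by camera).

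All 34 measured genes of mitosis and G2/M had a lower mean after 6-shogaol, with a median of -0.42 on the log2 scale. Of these 1 fell, 0 rose and 33 did not pass over all genes, while 28 fell when adjusted over the list alone. Of 37 measured DNA replication and G1/S genes 36 had a lower mean, the exception being CCNE1 (0.05, not past the threshold), with a median of -0.45. Here 1 fell, 0 rose and 36 did not pass over all genes, and 25 fell when adjusted over the list alone. The genes that fell were BIRC5, the mitotic and anti-apoptotic protein survivin, 1.55-fold lower (adjusted p = 0.0457 by limma), and CDC45, a component of the replicative helicase, 1.55-fold lower (adjusted p = 0.0464 by limma). The kinetochore gene NDC80, the transcription factor FOXM1, the spindle gene ASPM, the helicase subunits MCM7 and MCM6 and the origin licensing gene CDC6 were 1.51-fold to 1.56-fold lower without passing. These lists had the smallest camera p of all at the preset correlation, with adjusted p = 7.19e-24 for mitosis and 4.50e-23 for replication. With an estimated correlation the camera adjusted p was 0.578 for both. That correlation was estimated at 0.43 for mitosis and 0.50 for replication, far above the preset 0.01.

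Metallothioneins, small metal-binding proteins, shifted down with a median of -0.27. Of 12 measured genes in the list 2 fell, 0 rose and 10 did not pass (6 fell when adjusted over the list alone). MT1X was 1.76-fold lower (adjusted p = 0.0166 by limma) and MT2A 1.72-fold lower (adjusted p = 0.0171 by limma), and MT1F and MT4 were 1.40-fold and 1.45-fold lower without passing. The members are close paralogues, and their probe sets may read each other's transcripts. The camera adjusted p was 5.13e-06 at the preset correlation, and adjusted p = 0.578 with an estimated correlation.

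Targets of the oestrogen receptor, which drives growth of this cell line, moved in both directions. Of 27 measured members 2 fell, 1 rose and 24 did not pass (5 fell and 1 rose when adjusted over the list alone), with a median of -0.16. CXCL12 and the fatty acid elongase ELOVL2 (1.62-fold) fell, and STC2 rose. MYBL1 was 1.53-fold lower without passing, and ESR1, which encodes the receptor, was 1.14-fold lower (adjusted p = 0.744 by limma). The camera adjusted p was 0.00383 at the preset correlation, and adjusted p = 0.727 with an estimated correlation. Without 6-shogaol replicate 2 the list no longer passed (adjusted p = 0.123 by camera), nor after renewed quantile normalisation (adjusted p = 0.0587).

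Targets of the PPAR nuclear receptors had a median of 0.11, and 1 of 26 measured members rose, 0 fell and 25 did not pass (3 rose when adjusted over the list alone). PDK4, the kinase that restrains pyruvate dehydrogenase, rose 1.82-fold (adjusted p = 0.0117 by limma). HILPDA, ANGPTL4 and UCP2 were 1.40-fold, 1.43-fold and 1.32-fold higher without passing, and PPARG itself was 1.19-fold higher (adjusted p = 0.598 by limma). The camera adjusted p was 0.00278 at the preset correlation, and adjusted p = 0.578 with an estimated correlation. Without 6-shogaol replicate 1 the list narrowly missed the threshold (adjusted p = 0.0564 by camera).

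Among the remaining lists that passed at the preset correlation, 0 members of the hypoxia, autophagy and lysosome, or cholesterol synthesis lists passed singly over all genes. In the hypoxia list (median 0.18, 25 measured, 6 risen when adjusted over the list alone) P4HA2 and VEGFA were both 1.45-fold higher and NDRG1 was 1.37-fold higher, and the camera adjusted p was 2.17e-05, with adjusted p = 0.578 with an estimated correlation. In the autophagy and lysosome list (median 0.19, 28 measured, 4 risen when adjusted over the list alone) WIPI1, GABARAPL1, HEXA and NEU1 were 1.44-fold to 1.57-fold higher, and the camera adjusted p was 0.000505, with adjusted p = 0.727 with an estimated correlation and 0.352 without 6-shogaol replicate 1. In the cholesterol synthesis list (median -0.17, 20 measured, 1 fallen when adjusted over the list alone) ACAT2 was 1.59-fold lower (adjusted p = 0.0506 by limma) and IDI1, STARD4 and DHCR7 were 1.32-fold to 1.33-fold lower. Its camera adjusted p was 0.00137, with adjusted p = 0.578 with an estimated correlation and 0.0658 without 6-shogaol replicate 2.

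In the mesenchymal list 2 of 24 measured genes rose, 0 fell and 22 did not pass (2 rose when adjusted over the list alone), namely ACTA2, smooth muscle actin, at 1.95-fold and the matrix protein TGFBI at 1.92-fold. Its median was 0.07. ITGA5 was 1.34-fold higher and CDH11 1.32-fold lower without passing. The camera adjusted p was 0.0302, and adjusted p = 0.647 with an estimated correlation. The call was lost without vehicle replicate 1 (adjusted p = 0.146), without 6-shogaol replicate 2 (0.908) and after renewed quantile normalisation (0.154).

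**Figure D2:**
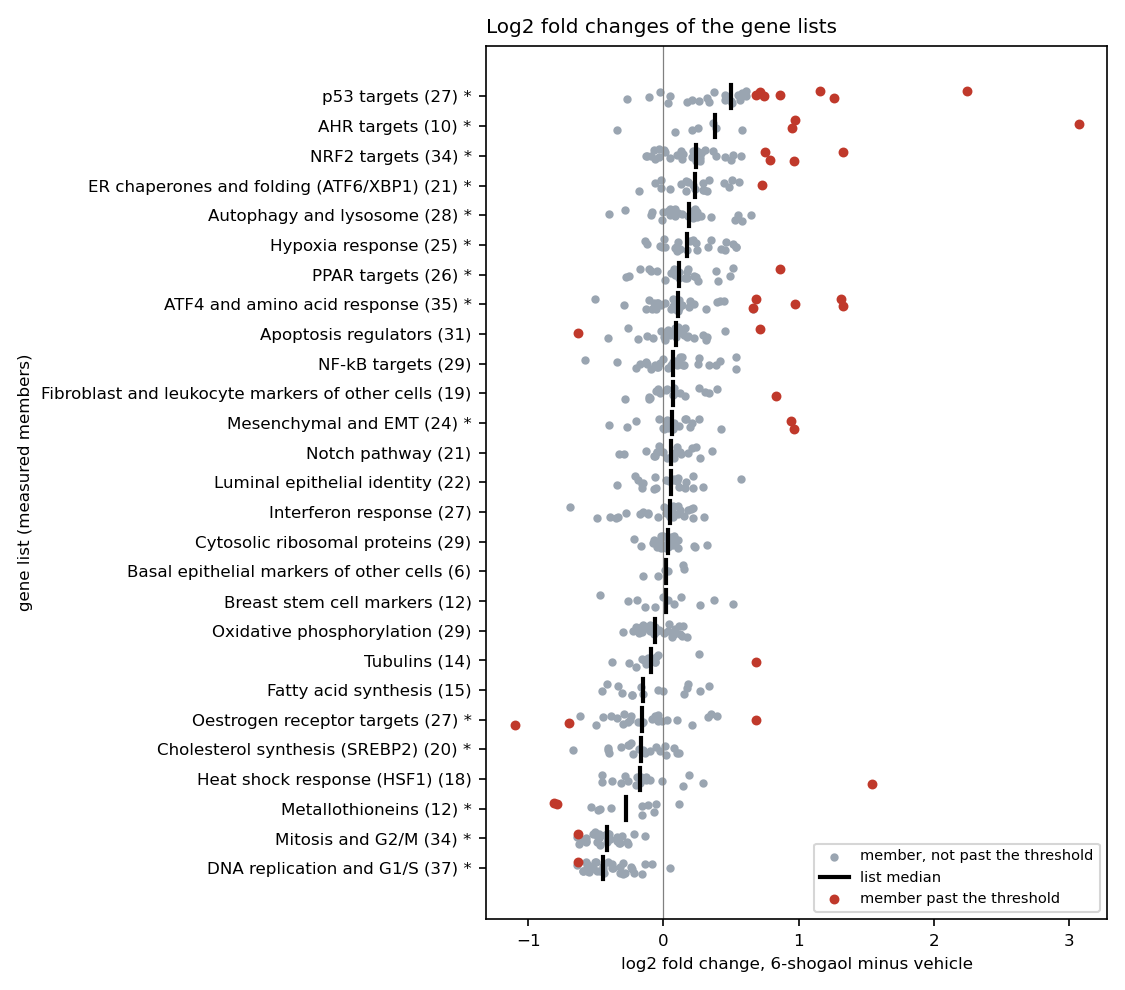
Log2 fold changes, 6-shogaol minus vehicle (x axis), of the measured members of the 27 gene lists (y axis, number of measured members in brackets, sorted by median). Each point is a gene, red where it passed the adjusted threshold over all genes, bars are list medians, and an asterisk marks the 14 lists that passed camera at the preset correlation; p53 targets lie at the top with a median of 0.50 and DNA replication genes at the bottom with -0.45.

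The other 13 lists did not pass camera on the deposited values of all 4 arrays without blocks. In the heat shock list HSPB8 rose, and 14 of 18 measured members had a lower mean, among them HSPA8, CACYBP and HSPE1, 1.30-fold to 1.37-fold lower without passing (list adjusted p = 0.0727 by camera, 0.0462 with replicates as blocks and 0.0116 without 6-shogaol replicate 1). Among apoptosis regulators, the death receptor FAS rose 1.64-fold and BIRC5 fell, while TNFRSF10B was 1.37-fold higher and CASP6 1.33-fold lower without passing (31 measured, list adjusted p = 0.127 by camera, and 0.00701 without 6-shogaol replicate 2). Of 14 tubulin genes TUBA4A rose 1.61-fold and 12 had a lower mean, with TUBB4A and TUBA1C 1.30-fold and 1.19-fold lower and TUBB2A 1.20-fold higher without passing (list adjusted p = 0.391 by camera). No member passed among the NF-kB targets, where NFKB1 was at -0.58 on the log2 scale and VEGFA 1.45-fold higher, or in the interferon response, where IFIH1 and HERC5 were 1.61-fold and 1.41-fold lower. The list adjusted p was 0.160 and 0.524 by camera. For the interferon list the median (0.05) differed in sign from the mean (-0.04) and from camera's direction, which was down. No member passed in fatty acid synthesis, where SCD and SREBF1 were 1.37-fold and 1.33-fold lower (list adjusted p = 0.215 by camera), or in the Notch pathway, where JAG1 was 1.28-fold higher and HEY2 1.26-fold lower (list adjusted p = 0.418 by camera).

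Of 22 luminal epithelial genes 0 passed singly, with ELF3 1.49-fold higher and TFAP2C 1.27-fold lower (list adjusted p = 0.512 by camera). In the breast stem cell list CD44 was 1.43-fold higher and ITGA6 1.38-fold lower without passing (0.813 by camera). Markers of other cell types gave an adjusted p of 0.847 for basal epithelium, where ITGB4 was 1.11-fold lower and DSG3 1.11-fold higher, and of 0.0881 for fibroblasts and leukocytes. The latter list passed upwards without vehicle replicate 2 (mean 0.17, adjusted p = 0.00892 by camera), without 6-shogaol replicate 1 (mean 0.15, adjusted p = 0.0293) and without the dimmest genes (mean 0.22, adjusted p = 0.0179), against a mean of 0.10 on all 4 arrays and all genes. In it 1 of 19 genes rose. This was CD68, a lysosomal membrane glycoprotein, at 1.79-fold (adjusted p = 0.0105 by limma), while MS4A1, CD14 and LYZ were within 1.31-fold of vehicle without passing. Ribosomal protein genes (RPS19 1.25-fold and RPLP2 1.17-fold higher, list mean 0.03, list adjusted p = 0.418 by camera) and oxidative phosphorylation genes (NDUFA9 1.23-fold and NDUFS3 1.17-fold lower, list adjusted p = 0.353 by camera) had 0 members past the threshold. The ribosomal list passed upwards after renewed quantile normalisation (mean 0.093, adjusted p = 0.0192 by camera) and without 6-shogaol replicate 2 (mean 0.090, adjusted p = 0.0453).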

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

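All tests here were planned except those with a robust prior and no trend, which were added after seeing the data. The called total (risen, fallen) was 172 (72, 100) on the deposited values. It was 304 (122, 182) with the replicate block, 592 (181, 411) with a trended and robust prior, 398 (145, 253) without the dimmest genes, 25 (16, 9) with a 2-fold minimum, and 1 (1, 0) after renewed quantile normalisation, with or without a robust prior. It was 0 (0, 0) in the unmoderated fit, where 1275 genes had an unadjusted p under 0.05, and 0 (0, 0) over all probe sets, where 2487 did, or 2475 with a robust prior. Leaving out 1 array gave 3 to 54 calls (2 to 34 risen, 0 to 25 fallen): 3 without 6-shogaol replicate 1, 4 without 6-shogaol replicate 2, 53 without vehicle replicate 2 and 54 without vehicle replicate 1, with the lone array assumed to vary like the other group. Median centring (226), probe set means (168) and a robust prior alone (168) kept the count within 1.5 times. All 172 genes kept their direction in every fit that held them. Most of these settings could not reverse it, since they use the same fold changes or leave out 1 array where the groups do not overlap. The prior degrees of freedom were 14.2 on the deposited values, 4.82 after quantile normalisation, 4.05 over all probe sets and 42.1 with the trended prior. The replicate numbers were not taken as pairs: same-numbered arrays' deviations correlated at 0.22 over genes, from a single pair of deviations, and under the block 13 more of the named genes and the heat shock list passed (the latter at adjusted p = 0.0462 by camera) while no call on a named gene or list was lost. Camera called 14 lists at the preset correlation, 0 with an estimated one and 0 with fry's directional test. Values that changed sign were all uncalled on the deposited values of all 4 arrays without a block. Over the fits that left out 1 array, NFE2L2 ranged from -0.020 to 0.19, ATF4 from -0.0034 to 0.17, DSG3 from -0.11 to 0.41, and the list means from -0.046 to 0.11 (luminal), -0.029 to 0.075 (stem cell), -0.11 to 0.16 (basal), -0.023 to 0.090 (ribosomal, which passed camera at its highest value, adjusted p = 0.0453) and -0.16 to 0.037 (heat shock, which passed at its lowest, adjusted p = 0.0116, and kept camera's direction). After quantile normalisation, with or without a robust prior, camera's direction turned for the basal list (mean 0.0051) and oxidative phosphorylation (mean 0.00898). The cause of these was not tested. The table gives no signal over background, so what dim probe sets can show is not known.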

Other observations

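The tests of the CYP1A1 and histone patterns were chosen after the results were seen, except the test of the histone genes without 6-shogaol replicate 2, and the test of the intensity trend was chosen before its result was seen.

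Histone genes of the H1, H2A, H2B, H3 and H4 families, most of them made in S phase, were not among the fixed lists. Of 57 measured, 8 fell, 0 rose and 53 had a lower mean after 6-shogaol, with a median of -0.39 on the log2 scale. H4C14 and H4C15 had the same fold change and SE, and their value is that median. The 57 may therefore not all be separate readings. H2BC14 was 1.86-fold lower (adjusted p = 0.00695 by limma), H1-5 1.69-fold, H4C4 1.67-fold and H3C12 1.66-fold. Among 43 measured genes of snRNP, hnRNP and SR splicing proteins, a family also chosen after the values were seen, 3 fell (HNRNPM, SNRPD1 and SNRPG), 0 rose and 38 had a lower mean, with a median of -0.29. In 2 adhesion and guidance families that held several called genes, members fell while the median stayed near 0. Of 19 semaphorins SEMA3A, SEMA3D and SEMA6A fell and 0 rose, with a median of 0.07, and of 32 cadherins and non-clustered protocadherins CDH12, CDH18, CDH26, PCDH7 and PCDH10 fell and 0 rose, with a median of 0.01. All of these families, the histones among them, were picked after their values were seen, so the camera tests run on them say nothing about a shift and are not used here.

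The first pattern is the number of called genes, 172 on the deposited values and 1 after renewed quantile normalisation. A smooth trend on intensity took up 16.6% of the variance of the difference between the 6-shogaol arrays, against 3.0% for the vehicle arrays. When that trend was removed, limma's prior degrees of freedom went from 14.2 to 4.52, close to the 4.82 after quantile normalisation, and 1 gene was called, although 2415 genes had an unadjusted p under 0.05. This is consistent with the trend adding a similar spread to many genes, which makes gene variances look more alike and strengthens the pooling. The number of calls may therefore be partly a product of array scaling. All 172 genes kept their direction after quantile normalisation, but every called change was at least 0.62 on the log2 scale. A reversal was therefore unlikely from the start, and the kept direction says little. The 4 arrays form only 3 splits into pairs, too few for a share under 0.05: 1 split, the real one, gave 172 calls and the highest of the others 0.

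The second pattern is the fall of the histone genes, a family picked after its values were seen. Transcripts of one class read by the probes of its copies would leave the other classes unmoved, but 4 classes (H1, H2B, H3 and H4) each held a gene that fell, so sharing within a class can inflate the count of genes without accounting for the whole. The fall did not depend on the narrow distribution of 6-shogaol replicate 2 alone, since without that array the median was still -0.32, against -0.39 with it. A smaller share of cells in S phase is a candidate explanation, and the replication and G1/S list moved with the histones (median -0.45, against -0.13 to 0.02 in 95% of 10000 lists matched on expression, which leave correlation between genes out of account). That median was known when the comparison was chosen, so the comparison adds little to it. The list did not pass fry's directional test (adjusted p = 0.188). It also did not pass camera with an estimated correlation (adjusted p = 0.578), which had little power in the simulated draws. No cell cycle measurement was analysed here, and mitotic genes had a median of -0.42, so a general loss of cycling cells stays open.

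The third pattern is the rise of CYP1A1. Its neighbour CYP1A2, a close paralogue, was at -0.34 (SE 0.23). The CYP1A2 probe set thus gave no sign of a rise in transcripts that the CYP1A1 probe set could read. How well the CYP1A2 probe set would show such a rise was not tested. For CYP1A1 the lower 6-shogaol array lay 2.46 log2 units above the higher vehicle array, so its rise does not rest on 1 array. Of the 10 measured AHR targets 9 had a higher mean and 1 a lower mean. Activity of the aryl hydrocarbon receptor is a candidate explanation: the other 9 measured AHR targets had a median of 0.37, above the range of -0.16 to 0.11 in 95% of 10000 lists matched on expression, which leave correlation between genes out of account. The AHR list median was known when this comparison was chosen, so the comparison adds little to it. The whole AHR list did not pass fry's directional test (adjusted p = 0.103). It also did not pass camera with an estimated correlation (adjusted p = 0.578), which had little power in the simulated draws. Some of these genes (NQO1, whose value is the median of the other 9, SLC7A5 and ALDH3A1) are also listed as targets of NRF2 or ATF4, so the lists overlap. Whether 6-shogaol acts through any of these factors was not tested.

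Among the 72 genes that rose, 69 changed more on 6-shogaol replicate 1 than on replicate 2 (median 0.92 and 0.66 on the log2 scale), and of the 100 that fell, 21 did (median -0.67 and -0.83). Most called genes of both directions thus read higher on replicate 1. Over all genes its upper quartile was higher than that of replicate 2 (8.12 against 7.99 log2 units) and its lower quartile lower (5.17 against 5.31). Array scaling and a difference in response were not told apart.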
